A study of Drosophila melanogaster with 2 samples.

How the data were processed

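Chromatin immunoprecipitation with sequencing was done on whole Drosophila melanogaster embryos, 0 to 24 h old, that carried a transgene for the homeodomain protein Rx fused to eGFP. Per the labels, the fusion protein was precipitated with an antibody against GFP, chromatin was sonicated, and the fragment size range was 200 to 800 bp. There were 2 samples, both in 1 group, which the labels call biological replicates 1 and 2. The labels name a possible control experiment, which was not analysed here. The aligner and the peak caller are not given in the sources used here.

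The data were 8 peak lists on the dm6 assembly, per the labels, of which 4 were thresholded on the irreproducible discovery rate (IDR) and 4 were longer ranked lists. Each replicate had a thresholded and a ranked list of its own, and the remaining lists were made for the whole series. The thresholded series-wide list that its name calls conservative was used as the main list, a choice made before the data were examined, as were the tests, motifs and gene lists below. The peak height in each list is the authors' signal value, whose scale is not stated, so it was used to describe and rank peaks within a list, and as a ratio between the replicates and along 2R. The deposited IDR score is a whole number whose lowest value was 830 in the 4 thresholded lists. The ranked lists also hold the authors' −log10 global IDR, and the lowest value among main-list peaks was 2.00, a global IDR of 0.01. The planned stricter threshold, a global IDR under 0.01, therefore removed no peak and tests nothing. The ranked list behind the main list gives a height in each replicate for every peak, in 2 columns not named by replicate. Signals given below for replicate 1 or 2 are therefore those of the highest overlapping peak in that replicate's own ranked list.

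No file gives read counts, so the sequencing depth of either replicate is unknown. Intervals on shares are 95% Wilson intervals over peaks or genes and cover counting error only. Peaks are not independent replicates, so p-values over peaks describe these lists and not the spread between embryo collections. The embryos' sex is not given in the sources used here, and no untagged embryos were analysed here.

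Positions are given 1-based on dm6. The highest peak end on each of the 7 chromosome arms lay within the length of that arm in the Release 6 reference genome. Genes were taken from Ensembl release 115 (BDGP6.54), and 13968 protein-coding genes on the arms were used. Peaks on unplaced scaffolds were left out of all tests but the comparison of replicate heights, which used all 3303 main-list peaks. Of 767 gene symbol entries in the fixed lists, 13 matched no gene of that annotation and were not analysed here.

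Replicate overlap was the share of thresholded peaks that overlapped a peak of the other replicate by at least 1 bp, compared with 1000 random placements on the same arm (one-sided permutation p, smallest possible 0.001). Replicate heights were compared by Spearman's rho across peaks with an interval from 1000 bootstrap draws. Each summit was assigned to the first fitting class of promoter (within 500 bp of a protein-coding transcription start), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic, and compared with 1000 random placements (two-sided permutation p, smallest possible 0.002). Arm counts were tested against the share of assembled length with exact binomial tests. Sequence was searched on both strands from 100 bp before to 100 bp after each summit. The background was windows of the same size centred 1000 bp to each side, leaving out those that overlapped a main-list peak. Fisher's exact test, two-sided, was applied to 30 fixed motifs and to all 6-mers. A gene was called bound when a summit lay in the gene or within 2 kb of it. For each of 28 fixed gene lists, the number bound was compared with 100000 draws of genes matched on length in 20 bins (two-sided permutation p, smallest possible 2e-05). The draws take genes independently, so for lists of neighbouring genes that can share a summit the p can be too small. P-values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05.

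The genes named in the text follow a rule fixed before the data were examined. They are Rx, hbn and otp, the genes nearest to or enclosing the 12 highest peaks, up to 4 bound genes with the highest peak in each list past the threshold, at most 2 such genes in other lists, and the 5 genes with most summits. One gene that the rule takes is not reported here. The motifs named are those past the threshold, and the 6-mers named are the 5 most enriched and the 5 most depleted. Any gene or sequence named outside this rule is marked as chosen after its values were seen.

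Alternatives were the other series-wide list, each replicate's own list, the 50% of peaks with the highest signal, other overlap criteria, promoter sizes, windows, flanks and backgrounds. The matched background took 5 random windows per peak with the same arm, promoter status and GC content in bins of 5 percentage points. Chosen after the data were seen were a global IDR under 0.001, the 6-mer and peak height tests on each replicate's own list, and matched windows of 50 bp either side, in all peaks and in the highest 10%. The gene groups, the positions of sequences around summits, and random windows matched on arm and promoter status alone, all in the closing section, were also chosen then. So was the profile along 2R, shown in the figure of the Rx locus and in the closing section.

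The location, motif, gene list and overlap tests were also run on simulated data. With 40% of 3250 summits put on transcription starts and the rest at random, the location test gave 46.4% in promoters, and with all summits at random it called 0 classes. With the homeodomain core put into 5% of random windows, the motif test gave an odds ratio of 1.45 and called it, and without it called 0 of 30 motifs. By construction random summits do not differ in GC from their flanks as the real summits do. Calls caused by base composition could therefore not show. With genes bound by length alone, the length-matched test called 0 of 28 lists and the test without matching called 3. Each gene was bound independently there, so calls caused by neighbouring genes that share a summit could not show. With 70% of 2000 simulated peaks shared, the overlap test gave 70.2%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.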

Results

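Binding of Rx-eGFP, a tagged form of the paired-class homeodomain protein encoded by the retinal homeobox gene, was profiled in whole embryos aged 0 to 24 h. There was 1 group with 2 biological replicates, so the comparisons are between replicates and between bound and unbound sequence. The main list held 3303 peaks, of which 3250 lay on the chromosome arms. Replicate 1 had 2438 peaks of its own and replicate 2 had 2209. The median width was 284 bp in the main list, and 86.1% of its peaks had that width. The 447 narrower peaks on the arms were taller, with a median signal of 284.2 against 81.6 for peaks of the median width. Read depth is unknown.

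Peaks recurred between the replicates. On the arms, 1647 of 2411 replicate 1 peaks overlapped a replicate 2 peak (68.3%, 95% Wilson interval 66.4 to 70.1%), and 1654 of 2176 replicate 2 peaks overlapped a replicate 1 peak (76.0%, 74.2 to 77.8%). Random placement shared 19.7 replicate 1 peaks on average and at most 36 (permutation p = 0.001, the smallest possible). Unshared peaks were lower, with a median signal of 42.4 against 76.5 for shared peaks in replicate 1 and 42.5 against 67.2 in replicate 2. Across the main-list peaks, which are not independent replicates, heights in the replicates had a Spearman's rho of 0.758 (bootstrap interval 0.740 to 0.774), and 96.1% of peaks were within a factor of 2. The main list was itself chosen on the rank of peaks in both replicates, which fixes part of these values. Over all 138548 ranked peaks rho was 0.287 and 67.6% were within a factor of 2. Of the 100 highest main-list peaks in either replicate, 81 were common to both.

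Of the 12 highest peaks, 11 lay at promoters. The highest, with a signal of 1838.1, was at X:2703748-2704020, with its summit 30 bp from a start of Ugalt, a UDP-galactose transporter gene. The next were at 3L:19590485-19590763 in the promoter of CG14100 (1719), at 3L:5139374-5139629 in that of Tcs5 (1382), at 2R:22514182-22514431 in that of px, a wing vein gene (1308), and at 2R:15217624-15217875 in that of mRpL41, a mitochondrial ribosomal protein gene (1124). The promoter of the Polycomb group gene ph-p held the sixth peak, X:2137238-2137475 (1116). The remaining 6 of the 12 highest peaks had signals from 936 to 1112. They lay at the promoters of CG7601, PNPase, the chromosomal protein gene Chro, CenG1A and Art3, and in an intron of CG11050. All 12 were in both replicates' own lists. The genes with most summits were all on X: kirre, a muscle founder cell adhesion gene, with 22, CG1677 with 16, CHES-1-like with 13, and Raf, a kinase of receptor tyrosine kinase signalling, and the nuclear receptor gene Hr4 with 11 each. These counts take no account of gene length: kirre spans X:2740384-3134532, and the shorter CHES-1-like X:7682338-7709385.

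Promoters were over-represented among summits and transcribed exons were under-represented. Of 3250 summits, 1387 (42.7%, 95% Wilson interval 40.99 to 44.39%) lay within 500 bp of a transcription start, against 11.5% on random placement, a ratio of 3.72. Coding exons held 1.29% against 13.9%, 3′ UTRs 0.80% against 4.53% and intergenic sequence 17.8% against 30.1% (adjusted permutation p = 0.0035 for each of these 4 classes, from 0.002, the smallest possible). Introns held 36.9% against 39.2% (adjusted permutation p = 0.00839), a difference that was lost when random positions avoided soft-masked sequence (adjusted permutation p = 0.224, range over the alternatives 0.0028 to 0.873). The share in 5′ UTRs, 0.615%, did not pass the test (adjusted permutation p = 0.373), but was lower than on placement past the threshold in replicate 1's own list (0.415%, adjusted p = 0.035) and with promoters of 1000 bp (0.185%, adjusted p = 0.014). The promoter share was 44.6% in replicate 1 and 45.8% in replicate 2. Among 4 groups of peaks ranked by height, the highest had 55.0% in promoters and the lowest 37.7% (Fisher's exact test, two-sided, p = 2.87e-12).

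**Figure D1:**
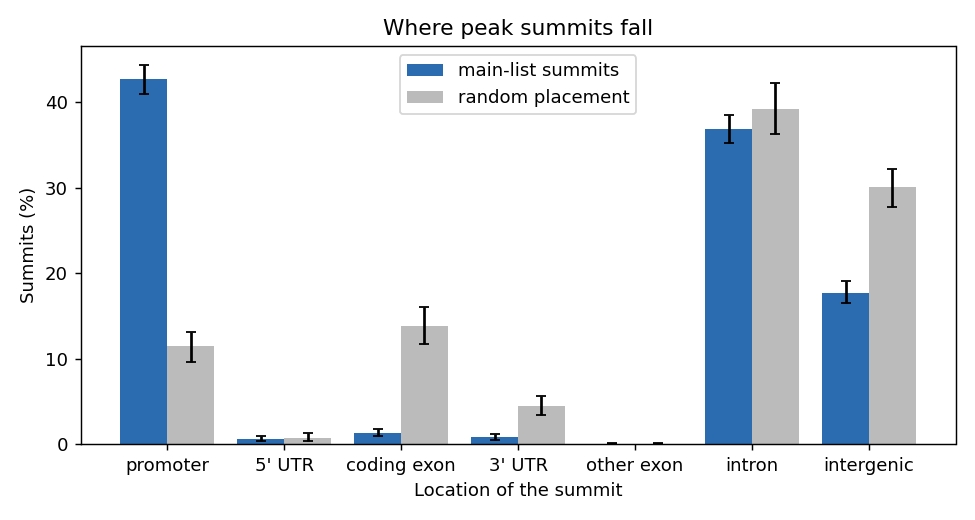
Share of main-list summits in each class of sequence (blue, 95% Wilson intervals) and of randomly placed summits (grey, mean with the lowest and highest of 1000 placements), in percent. Promoters hold 42.7% of summits against 11.5% on placement, and coding exons 1.29% against 13.9%.

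Chromosome 4 and Y were nearly free of peaks. Each held 3 peaks, 2.23 per Mb on 4 (0.0942 of the count its length predicts, exact binomial test, adjusted p = 6.16e-10) and 0.818 per Mb on Y (0.0346, exact test, adjusted p = 9.84e-33). The X had 640 peaks, 27.2 per Mb, a ratio of 1.15 (exact binomial test, adjusted p = 0.00031). The ratio on 2L was 1.09 (exact binomial test, adjusted p = 0.0347), with an adjusted p of 0.0519 to 0.294 in the 5 alternatives tried. The share of 4 and Y that could be mapped is not given in the sources used here.

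The CTCF-like, DRE and M1BP motifs had the highest odds ratios of the fixed motifs. The CTCF-like motif was in 2.55% of 3250 summit windows against 0.367% of 6262 flanking windows (odds ratio 7.11, Fisher's exact test, adjusted p = 7.64e-20), the DRE, bound by the promoter factor Dref, in 2.68% against 0.463% (5.91, adjusted p = 1.35e-18), and the core promoter motif of M1BP in 0.892% against 0.176% (5.12, adjusted p = 3.23e-06). Against windows matched on GC, arm and promoter status these odds ratios were 8.16, 2.10 and 2.65, all past the threshold. The homeodomain core TAATTA was in 15.4% of summit windows against 11.9% of flanking windows (odds ratio 1.35, Fisher's exact test, adjusted p = 7.12e-06). Summit windows had 37.5% GC against 42.8% in the flanks, and against windows matched on GC the core was in 15.4% and 15.9% (odds ratio 0.964, Fisher's exact test, adjusted p = 0.637). The paired-class P3 and P2 dimers had odds ratios of 1.85 and 1.75 against the flanks (Fisher's exact test, adjusted p = 0.000168 and 0.00202), which were 1.25 and 1.16 in matched windows (adjusted p = 0.124 and 0.414).

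The 3 AT-content control words, chosen to stand for no factor, had odds ratios of 2.20, 2.00 and 1.58 against the flanks, each above that of the homeodomain core. The third, TATATA, resembles the TATA box word TATAAA, so it may not be free of a factor. The TATA box had 1.94, forkhead 1.36 and BEAF-32 1.302. In matched windows the controls had 1.27, 1.36 and 1.06, the TATA box 1.16, forkhead 1.13 and BEAF-32 1.16, and the calls of the third control and forkhead were lost (Fisher's exact test, adjusted p = 0.415 and 0.071). The CA repeat (0.691) and Runt (0.778) were the 2 of 30 motifs that were lower, and 12 were higher. With flanking windows of 200 bp either side the CA repeat was instead higher (1.21, Fisher's exact test, adjusted p = 0.00249). In matched windows neither the CA repeat nor Runt was lower past the threshold. There 9 were higher, among them the E-box CAGCTG (1.52, Fisher's exact test, adjusted p = 1.05e-08) and the GAGA factor motif (1.66, 4.58e-05), which had 1.05 and 0.949 against the flanks, and 5 were lower: K50 homeodomain (0.769), Hox-Exd (0.855), Sox (0.882), nuclear receptor (0.684) and TCF (0.630). Outside promoters the odds ratios of DRE, BEAF-32 and M1BP were 0.337, 0.949 and 0.478, none past the threshold. That of the homeodomain core was 0.996 outside promoters and 2.18 in promoter peaks, where those of the AT-content controls were 1.91 to 3.35. The CTCF-like motif passed the threshold in 10 of 11 alternatives, with odds ratios of 4.83 to 13.2, and missed it in windows of 50 bp either side of the highest 10% of peaks (6.33, Fisher's exact test, adjusted p = 0.132).

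**Figure D2:**
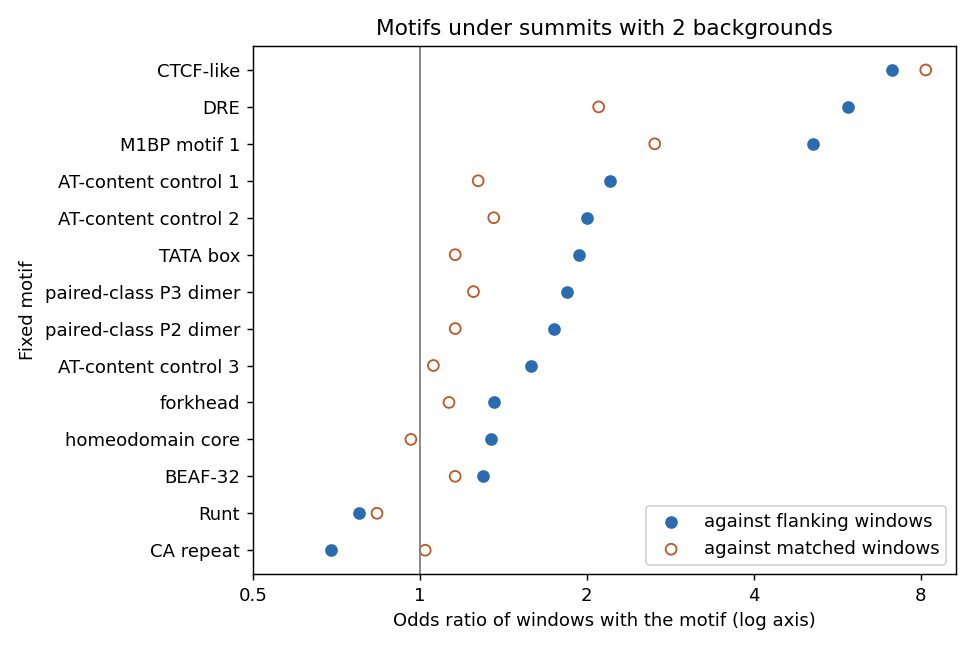
Odds ratio of windows with each fixed motif past the threshold, on a log axis, at summits against flanking windows (filled) and against random windows matched on GC, arm and promoter status (open). The homeodomain core is at 1.35 against flanks and 0.964 against matched windows, and the CTCF-like motif at 7.11 and 8.16.

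The 6-mer most enriched in summit windows belonged to none of the fixed motifs. ACAGTG was in 22.0% of summit windows and 7.89% of flanking windows (odds ratio 3.30, Fisher's exact test, adjusted p = 3.62e-78), and its odds ratio was 3.52 against matched windows. The next were ACACTG (2.87), AGTGTA (2.73), GTGCAC (2.68) and ACTGTA (2.48). The most depleted were CGAGGA (0.278), CCAGGA (0.321), CCGGAG (0.326), CTCCTC (0.331) and GACTCC (0.347), all of which were also below 1 in matched windows. In all, 479 6-mers were higher and 847 lower than in flanks, against 327 and 367 with matched windows. Peak height went with 1 of the 30 fixed motifs, the first AT-content control, which was in 47.0% of windows in the highest of 4 height groups and 36.2% in the lowest (Fisher's exact test, adjusted p = 0.000349). That call was lost in non-promoter peaks and in replicate 1's own list (Fisher's exact test, adjusted p = 0.192 and 0.099, range over the alternatives 2.59e-09 to 0.192). The homeodomain core was in 15.9% and 13.9% of the same groups (Fisher's exact test, adjusted p = 0.618).

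Ribosomal protein genes had the highest ratio of bound to expected genes of the 28 lists, and cuticle protein genes were the 1 list bound less often than expected past the threshold. A summit lay in or near 3699 of 13968 protein-coding genes (26.5%). Of 92 ribosomal protein genes, 62 were bound against 18.3 expected from genes of the same length (ratio 3.39, adjusted permutation p = 0.00056, from 2e-05, the smallest possible), with 55 in replicate 1 and 58 in replicate 2. Among the highest peaks were those at RpL7 (2L:10200951-10201135, signal 444.9), RpS27 (3R:25247415-25247604, 427.4) and RpL34b (3R:9401203-9401358, 330.4). These 3 lay in promoters. Of 100 cuticle protein genes, 5 were bound against 19.003 expected (ratio 0.263, adjusted permutation p = 0.00168). Neighbouring cuticle genes can share a summit or jointly lack any, which the draws ignore, so this p can be too small. The call for cuticle protein genes was lost with the nearest start and with no flank (adjusted permutation p = 0.0637 and 0.953, range over the alternatives 5.03e-07 to 0.953). The bound genes included Cpr76Ba, with an intergenic peak of 379.9, and Cpr31A (164.6), whose peak lay in an intron of Pen and nearest to a start of Pen. Cpr64Aa and Cpr64Ab share a peak of 70.5 in an intron of CG43367.

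Of 26 Polycomb and trithorax group genes, which maintain silent and active chromatin states, 17 were bound against 9.36 expected (ratio 1.82, adjusted permutation p = 0.0238). Their highest peaks were those at ash1, ph-p, Caf1-55 and phol (1719, 1116, 936 and 813.8), and the peaks at ash1, Caf1-55 and phol were nearest to starts of the neighbouring genes CG14100, Art3 and CG3437. The call was lost with the other series-wide list (adjusted permutation p = 0.0504), the nearest start (0.136) and a flank of 10 kb (0.963), and the lowest p over the alternatives was 0.000253. Of 35 genes of EGF, FGF, Wnt and BMP signalling, 24 were bound against 14.3 expected (ratio 1.68, adjusted permutation p = 0.0131), among them Med and Mad, which encode BMP signal transducers, the BMP ligand gene gbb, and aos, an inhibitor of EGF signalling. Their peaks had signals of 689.9, 273.3, 602.1 and 353.2, and those at Med and gbb were nearest to starts of Mnat9 and eIF6. That call was lost in the lists of replicates 1 and 2 (adjusted permutation p = 0.428 and 0.134), in the other series-wide list (0.104), in the 50% of peaks with the highest signal (0.110) and with a flank of 10 kb (0.436), and the lowest p over the alternatives was 2.13e-06.

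The lists nearest to the known roles of Rx in head and brain development did not pass the test. Bound were 6 of 20 eye specification genes (7.87 expected), 6 of 28 phototransduction genes (9.35), 7 of 17 head patterning genes (5.94), 7 of 29 neural homeobox and POU factor genes (12.017), 5 of 26 neuroblast and proneural genes (8.42), 11 of 34 neuronal function genes (15.1), 16 of 35 axon guidance genes (17.2), 3 of 35 neuropeptide genes (8.82) and 5 of 15 glial genes (5.39). With each summit given to its nearest start alone, head patterning had a ratio of 2.21 (9 of 17 bound, 4.07 expected, adjusted permutation p = 0.0875). The other lists just named then had, in the same order, ratios of 1.23, 0.471, 0.900, 1.06, 0.530, 1.13, 0.353 and 1.08, none past the threshold. Examples of bound genes are norpA, which encodes the phospholipase C of phototransduction, with a peak of 396.8 in an intron, elav, a neuronal RNA-binding protein gene, with 336.9 at its promoter, and hth with 162.4 in an intron. Of the remaining lists, 12 of 25 Notch pathway and E(spl) genes were bound (6.96 expected), 10 of 22 dorsoventral (7.89), 7 of 20 mesoderm and muscle factor (7.21), 6 of 23 muscle structural (8.49), 7 of 16 segment polarity (6.24), 6 of 15 gut (5.61), 5 of 14 trachea and salivary gland (5.58), 5 of 17 blood cell (6.37), 3 of 18 germ line (6.20), 2 of 10 pair-rule (3.14), 2 of 8 Hox (4.06), 1 of 8 gap (2.49), 12 of 48 proteasome (10.1), 0 of 16 yolk, chorion and vitelline genes (2.79) and both other genes of the 57B homeobox cluster (0.786). None of these passed the threshold. With a flank of 10 kb, 22 of 25 Notch pathway and E(spl) genes were bound against 12.6 expected (ratio 1.74, adjusted permutation p = 0.00168, range over the alternatives 0.00168 to 1). Neighbouring genes of the E(spl) complex can share a summit at that flank, which the draws ignore, so this p can be too small.

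**Figure D3:**
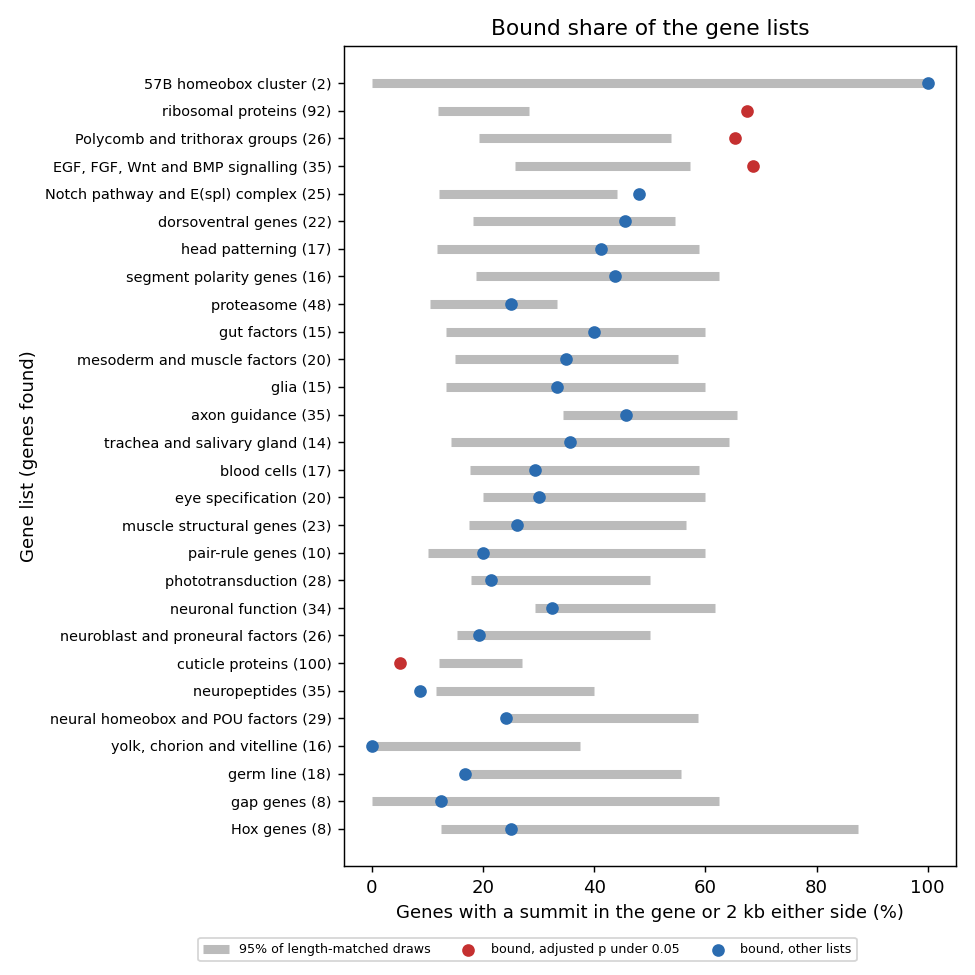
Percent of genes with a summit in the gene or within 2 kb (points, red where the adjusted p is under 0.05) and the central 95% of length-matched draws (grey bars) for the 28 gene lists, with the number of genes found in brackets. Ribosomal protein genes lie at 67.4% and cuticle protein genes at 5%.

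The tagged gene itself carried a low peak, and its neighbour otp one of the highest. Rx (2R:20916753-20937030) lies between the homeobox genes otp (2R:20883625-20903414) and hbn (2R:20954668-20960909), and the region from 10 kb before otp to 10 kb after hbn held 11 main-list summits, 2 of them in overlapping peaks. The peak in Rx, in a coding exon at 2R:20917127-20917410, had a signal of 59.8, ranked 2653 of 3250, and was in neither replicate's own list. The other series-wide list lacks it and has different peaks in Rx, at 2R:20922720-20923003 (35.1) and 2R:20928842-20929125 (53.4). A coding exon of otp held a peak at 2R:20884480-20884709 with a signal of 873.1, ranked 15, and 364.8 and 505.3 in replicates 1 and 2. In hbn the higher of the peaks, in a coding exon at 2R:20955009-20955292, had 71.8 and was in the list of replicate 1 alone. The replicates' own lists held 8 and 3 summits in the region. Reads from the transgene can map here, and a copy of the locus cannot be told from the endogenous one in these lists.

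**Figure D4:**
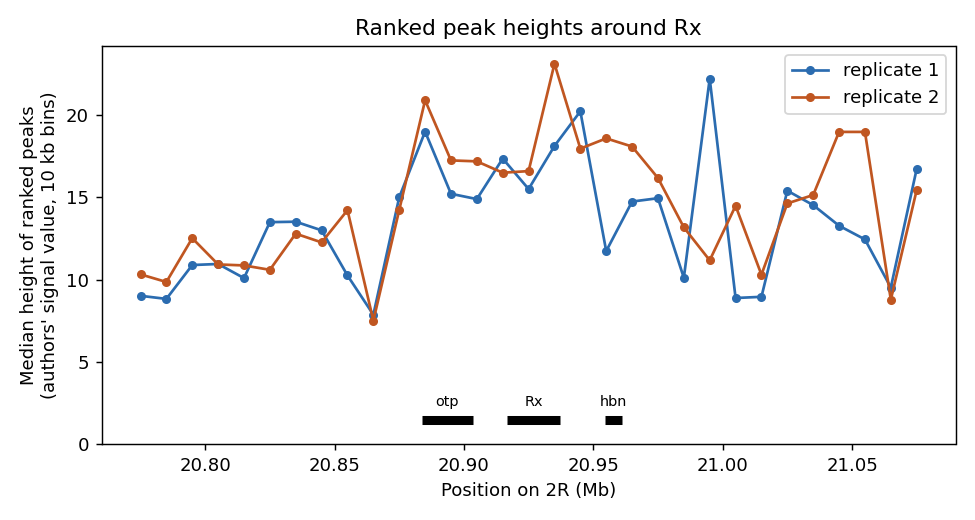
Median height of all ranked peaks in 10 kb bins along 2R around Rx in replicate 1 (blue) and replicate 2 (orange), in the authors' signal value, with the genes otp, Rx and hbn as black bars. Over the region the medians are 15.9 and 18.0, against 11.4 and 12.7 in the 100 kb on either side, where single bins reach similar heights. The profile was chosen after the data were seen.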

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

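In data that the comparisons did not use, 122 peaks of the ranked list behind the main list had a score at or above the lowest main-list score of 830 and were absent from the main list. Of these, 48 lay on 3R and 37 on unplaced scaffolds. Their median signal was 81.3, against 89.6 in the main list. The highest were named after their values were seen. An intronic peak with 1448 (2L:480957-481231), which would rank 3 on the arms, lay within ush and nearest to a start of cbt, a zinc finger factor gene. An intronic peak nearest to a start of Lk6 (3R:11760925-11761147) had 949.4, and a promoter peak at larp (3R:28326492-28326694) had 594.6. Soft-masked sequence made up 22.5% of those on the arms and 18.9% of main-list peaks.

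A further 53 main-list peaks lay on unplaced scaffolds, which were used only in the comparison of replicate heights. All 53 were on scaffolds assigned to X, over 48 scaffolds, with a median signal of 67.5 and a highest of 595.7.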

How the results depend on the processing

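A global IDR under 0.001, the 6-mer and height tests on each replicate's own list, and matched windows of 50 bp either side, in all peaks or the highest 10%, were chosen only after the results were seen. Over all results and alternatives, counting of the gene lists only those past the threshold, 309 values kept their direction and side of the threshold, or moved little where there was no test, 47 were weaker, 2 stronger (both for 5′ UTRs), 25 moved and 18 reversed. Replicate overlap, the promoter share and the ribosomal protein genes stayed past the threshold in every alternative run: the share of replicate 1 peaks shared was 61.5 to 78.2%, and the ratio for ribosomal protein genes 1.70 to 6.75. For the changes below the cause was not tested, except that fewer peaks were used in each replicate's list, in non-promoter peaks, in the 50% or 10% of peaks with the highest signal and at the stricter IDR. Leaving out a replicate means using the other one's own list. What depth limits is unknown, since no read counts were used.

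A global IDR under 0.001 left 1697 peaks. Spearman's rho between replicates was 0.706 in the other series-wide list and 0.720 in the 50% of peaks with the highest signal. Introns held 40.98% of summits with promoters of 250 bp, above random placement, where the share moved from promoters to introns by construction. Of the arms, 1 and not 2 was higher in the other list, the higher 50%, length without soft-masked sequence, and without either replicate (1 to 1). The ratio of 2R, never past the threshold, was 0.948 to 1.01 without a replicate.

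The number of fixed motifs higher was 5 in non-promoter peaks, 7 in matched windows of 50 bp either side and 0 in such windows of the highest 10% of peaks. The number lower was 4 in the other list, 5 with 50 bp and 4 with 200 bp either side, 5 in matched windows, 1 in non-promoter peaks, 0 in the narrow matched windows of the highest 10%, and 3 to 4 without a replicate. Reversed odds ratios in matched windows were 0.964 for the homeodomain core and 1.02 for the CA repeat, which was 1.21 with 200 bp either side (Fisher's exact test, adjusted p = 0.00249). In matched windows of 50 bp either side they were 0.909 for the core, 0.857 for the P3 dimer, 0.964 for forkhead and 0.963 for the third AT-content control. In the highest 10% of peaks they were 0.923 for the core, 0.479 for P3 and 0.665 for DRE. In non-promoter peaks they were 0.996 for the core, 0.337 for DRE, 0.949 for BEAF-32 and 0.478 for M1BP. Of these, the CA repeat with 200 bp either side alone passed the threshold in the reversed direction. With matched windows 367 6-mers were lower.

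The number of motifs more frequent in high peaks was 2 in the other list, 0 in non-promoter peaks and 0 to 1 without a replicate. The odds ratio of the homeodomain core with height, never past the threshold, was 0.948 in non-promoter peaks and 0.918 to 1.31 without a replicate.

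The number of gene lists bound more often, 3 in the main analysis, was 1 with the other series-wide list, and 2 in either replicate's own list, in the higher 50%, with the nearest start and with a flank of 10 kb, where the Notch list was 1 of the 2, and the number bound less often was 0 with the nearest start and 0 with no flank (0 kb). EGF, FGF, Wnt and BMP signalling had ratios of 1.49 in the other list, 1.75 in the higher 50%, 1.23 with a flank of 10 kb and 1.45 to 1.63 without a replicate, none past the threshold. Cuticle proteins had 0.275 with the nearest start and 0.288 with no flank. Polycomb and trithorax groups had 1.75 in the other list, 1.87 with the nearest start and 1.18 with a flank of 10 kb. The planned global IDR under 0.01 removed no peak.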

Other observations

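All gene groups in this paragraph were chosen after the fixed lists had been seen. Of 73 mitochondrial ribosomal protein genes, 29 were bound against 12.1 expected (ratio 2.39), with 26 in replicate 1 and 21 in replicate 2. Of 17 genes for insulator and promoter-binding proteins, 10 were bound against 4.90 expected (ratio 2.04, and 2.26 and 2.18 in replicates 1 and 2). For both groups peaks of some members were known when the group was made, so no p is given. Translation factor genes (18 of 51 bound, 13.6 expected) and heat shock protein genes (7 of 19, 4.78 expected) did not pass the test.

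ACAGTG, the most enriched 6-mer, lay more often beside the summits than under them, which was noticed in the data and then counted. Of its 856 occurrences in summit windows, 14.5% lay within 25 bp of the summit, against 26.2% of 522 in flanking windows. From 50 to 100 bp away it was 3.81 times as dense as at 300 to 500 bp, and within 50 bp 1.93 times. In the highest 10% of peaks these ratios were 6.41 and 1.12. The CTCF-like motif was most dense within 50 bp, at 6.32 times its density far away. The homeodomain core was 1.45 times as dense within 50 bp and the first AT-content control 2.04 times, and in the highest 10% of peaks 1.86 and 3.10 times. From 50 to 100 bp away the core had 1.14 and the control 1.64 times, and in the highest 10% of peaks 0.857 and 1.71 times.

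For the patterns below, the test of base composition and that of chance clustering were chosen after the result was seen, and the tests in non-promoter peaks and the highest 10% of peaks after the value for all peaks was known. The explanations tested are technical. The design gives no untagged group, so no biological explanation was tested. The homeodomain core was no more frequent at summits than in windows matched on GC, with an odds ratio of 0.964 (95% interval 0.867 to 1.07), and with arm and promoter status matched but not GC it was 1.33 (1.19 to 1.48), so that excess is consistent with base composition. Against flanks, the core had 2.18 in promoter peaks and 0.996 outside promoters, against random windows without GC matching 1.60 (1.36 to 1.88) and 1.16 (1.00 to 1.34), and with it 1.09 (0.924 to 1.27) in promoter peaks. Sites hidden by promoter peaks were argued against by an odds ratio of 0.881 in non-promoter peaks (0.763 to 1.01), and sites only under the highest peaks by 0.870 in the highest 10% of peaks (0.613 to 1.21). Windows of 50 bp either side, tried because the core was seen to be concentrated near summits, gave 0.909. Sites bound in few cells of the embryo, or without this core, stay open and were not tested.

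Peaks at ribosomal protein genes could come from a technical preference for promoters that are open in every cell. If so, other such groups should each be bound at over 1.5 times their expected number. The groups were chosen after the fixed lists were seen, in which proteasome genes already fell short at 1.19 (12 of 48 bound). Mitochondrial ribosomal protein genes were, at 2.39, but translation factor genes had 1.32 times and oxidative phosphorylation genes 1.25 times their expected number. These lists of 51 and 80 genes are too small to tell such ratios from 1.5. The share of oxidative phosphorylation genes bound (19 of 80, 95% interval 15.8 to 34.1%) lay below the interval for ribosomal protein genes (57.3 to 76.1%). That argues against a like excess at all such promoters. A preference for some promoters stays open. The DRE and M1BP motifs had odds ratios of 2.10 and 2.65 against windows matched on GC, arm and promoter status. Of the 62 bound genes, 53 (85.5%, 74.7 to 92.2%) had a summit within 500 bp of a start of their own, though a neighbour's start can lie as near. With each summit given to its nearest start alone, 51 of 92 ribosomal protein genes were bound against 10.2 expected (ratio 5.01). These values argue against summits of neighbouring genes as the source of the excess. A dependence on the level of transcription, which was not measured here, and signal of any tagged protein at such promoters stay open.

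The 11 summits from 10 kb before otp to 10 kb after hbn may reflect the transgene. As many summits were found in 0.8% of 1000 random windows of that length on 2R, which held 2.15 on average, which argues against chance clustering in the main list. In the replicates' own lists the shares were 0.9% for the 8 summits of replicate 1 and 23.8% for the 3 of replicate 2, so chance was not argued against in replicate 2. Around Rx, the median height of 60 ranked peaks was 30.4, at percentile 98.5 of 987 random windows (95th percentile 23.9). Extra copies of the locus would give such heights if the signal value does not correct for copy number, which is not stated. Heights over the whole region were 1.40 and 1.42 times those of the 100 kb on either side in replicates 1 and 2, a profile looked at after the cluster was noticed, and single bins outside the region were as high, so binding of Rx at its own locus stays open beside extra copies.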
